A study of Mus musculus with 295 samples.

How the data were processed

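RNA from the adipose tissue of 295 F2 mice was hybridised to 2-colour arrays, 1 array per mouse. The F2 mice came from a cross of the C57BL/6J and C3H/HeJ inbred strains, both lacking ApoE, and were fed a high-fat Western diet from week 8 to week 24 of age, per the series text. Each mouse's RNA carried Cy3, and a common pool of equal portions of all the RNAs carried Cy5, per the labels. The series text gives 295 mice, the text of the single samples gives 330, and 295 arrays were analysed. The number of 1 sample differs between its title and its source name, and the number in the title was used. Both sexes were present, but the labels do not say which mouse is of which sex, and they give no genotype or body weight. All mice therefore form 1 group and no groups were compared.

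The values are log10 ratios as deposited by the authors, for 23387 probes. How the intensities were corrected and normalized is not given in the sources used here. The scale, the centring and the direction are not stated either, and were read from the values. Deposited values ran from -2 to 2, and 527 lay at a limit, which on a log10 scale is 100-fold. Array means lay between -0.00991 and 0.0250, so the arrays look centred on their mean, and array medians ran from -0.0521 to 0.0387. A pool of equal portions makes the mean linear ratio of a probe close to 1, so the mean log ratio falls with the variance for mouse over pool and rises for pool over mouse. The slope over probes was -1.63 ± 0.13 (SD of 100 bootstraps), against -1.15 for log10, -0.50 for natural log and -0.35 for log2, all mouse over pool. The direction follows from its sign. The base is less certain: the slope is steeper than that of any base and nearest to log10. Over the 2290 most variable probes the median of the mean linear ratio was 1.05 read as log10, 0.97 as log2 and 0.97 as natural log, which does not separate the bases. Over the 229 most variable probes, a check chosen after the data were seen, it was 1.02, 0.80 and 0.77. All fold sizes below rest on the log10 reading, while correlations, adjusted p-values and counts of calls do not depend on it. Of 43365 pairs of arrays, 944 had an r under -0.3 over all probes (lowest -0.52, median 0.37, highest 0.90). Each of those 944 pairs had an array on each side of a split in epididymis transcripts described in the report. The labels state the dyes, and mice set against their own pool differ from it in opposite ways, so the direction was kept.

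Deposited values were multiplied by 3.32 to give log2 ratios. Values were missing for 1.02% of the table. Probes measured in at least 90% of the mice were analysed, which kept 22894 and left out 493, and the 7762 gaps that remained were filled with the probe's mean. Among those left out were the probes of Fabp4, Lpl and Cd36, with no value on 75.6%, 74.9% and 78.3% of the arrays. Probes were named through the platform's annotation, updated through Entrez gene identifiers to the RefSeq genes of GRCm38.p6, where 12652 matched. Of all probes, 13644 had 1 symbol, 48 had several and 9695 had none in that annotation. A gene was represented by its most variable probe with 1 symbol, which gave 11454 genes, of which 1267 had several probes. Arrays give no read depth, and precision is limited by the number of arrays.

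Before the data were examined, 27 gene lists with 430 genes were fixed, of which 299 were measured and stood in a single list. They cover adipocytes, fatty acid synthesis, cholesterol synthesis, adipose expansion, oxidative phosphorylation, fatty acid oxidation, thermogenesis, macrophages, MHC class 2, T cells, B cells, the interferon response, the acute phase, extracellular matrix, endothelium, the cell cycle, immediate early genes, heat shock, the morning and evening arms of the clock, ribosomal proteins, skeletal muscle, epithelium, epididymis, exocrine pancreas, liver and erythrocytes. A list score is the mean z-score of its members over mice. Named genes were chosen by a rule fixed at the same time: the 20 genes with the largest SD, the 12 most positive and 12 most negative correlations with Lep and with the macrophage score among those past an adjusted p of 0.05, the 3 members of each list most correlated with the regressor or the list, Lep and Apoe, and the 10 adjacent gene pairs with the largest absolute r that do not share a symbol root.

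Each probe was fitted on the Lep log ratio, and on the macrophage score, with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over probes. List coherence was compared with 10000 random lists matched on SD (one-sided, smallest possible p 0.0001). Correlations of list scores and of Lep with list scores were tested with 100000 permutations (two-sided), where the smallest possible p is 1e-05. Neighbouring genes were taken from the RefSeq gene order only, and tested against 1000 random gene orders. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used for the rest. On simulated data of 22894 probes for the Lep fit, 4% of planted correlations of 0.15 were recovered, 34% of 0.2, 94% of 0.3 and 100% of 0.5, with 7 false calls. Those probes were simulated independently, 200 of them with a planted correlation, whereas real probes vary together and most were called. The recovered shares and false calls therefore do not carry over to the real fit. In the real fit an r of 0.13 passed (Rhd, adjusted p = 0.0408), and the highest of 100 reassignments of Lep called 822 probes. The list tests on 11454 simulated genes recovered 9 of 9 planted lists and 36 of 36 planted pairs with 0 false calls, and the neighbour test on 10618 simulated genes recovered 194 of 200 planted pairs.

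The plan had named Xist beside Y-linked genes as a covariate. No probe is named Xist in the annotation used, so the mean of Eif2s3y and Kdm5d was used alone, and a planned split by Xist was replaced by one by Eif2s3y. Alternatives covered array centring, the covariates, other spreads and log bases, ranges of mouse numbers, odd and even numbers, rank correlation, other regressors, other scores and probe choices, and sets of mice without the arrays with epididymis transcripts.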

Results

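Adipose tissue mRNA was measured in 295 F2 mice, each on 1 array against a pool of all the RNAs, so that every value is a mouse's level relative to the average of the cross. The labels name no groups within the cross. The quantities the design gives are therefore how widely genes vary from mouse to mouse, which genes vary together, and whether genes close on a chromosome do, in a cross set up to study the genetics of gene expression. Splits of the mice by Eif2s3y and by epididymis transcripts, and the values within them, were chosen after the data were seen. Arrays were not repeated, so the spread over mice contains technical error.

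Eif2s3y, a Y-linked translation factor gene, had the largest SD of any gene, 3.29 ± 0.14 (SE, n = 295 mice) on the log2 scale. Crisp3, a secretory protein gene, had an SD of 3.25 ± 0.13, and its central 90% of mice spanned 645-fold. Sult1e1, the estrogen sulfotransferase, had an SD of 2.88 ± 0.12 and spanned 124-fold. C4bp, Epp13, Spink10, Spag11a, BC048679, Cuzd1, Ces5a, Lcn8, Kdm5d, Mmp7, Cldn3, Mgarp, Lcn9, Agr2, Adam7, Hsd3b1 and Ido1 completed the 20 most variable genes, with SDs between 2.43 and 3.12. Lep, the leptin gene, had an SD of 0.46 ± 0.02 and a 2.95-fold span, and Apoe, which the parental strains lack as a functional gene, an SD of 0.45 ± 0.02 and a 2.70-fold span.

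Across all 22894 probes the median SD was 0.29, and the central 90% of mice spanned at least 2-fold for 8968 probes (39.2%) and at least 4-fold for 1743. Members of the fixed lists differed in spread. The median SD was 2.12 for epididymis genes, 1.46 for epithelium, 0.83 for B cells, 0.82 for thermogenic genes and 0.80 for macrophages, against 0.50 for adipocyte genes, 0.30 for oxidative phosphorylation and 0.23 for the morning arm of the clock. Ucp1, the uncoupling protein of brown fat, had an SD of 2.14 and spanned 89.5-fold. The count of 8968 depends on the log base: read as log2 it is 519, and as natural log 1270. For the 1267 genes with several probes, the median r of the 2 most variable probes was 0.24 over mice against -0.0027 for random pairs of like SD, and it was 0.45 for the 384 genes with both probes above the median SD.

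Transcripts of epididymis stood apart in 48 of the 295 arrays. The epididymis score of those arrays was at least 1.61, and that of the other 247 at most 0.45. Over all mice, the log2 ratio of Lcn8, an epididymal lipocalin, ran from -5.66 to 2.85, that of Lcn9 from -6.12 to 2.58, that of Adam7 from -6.29 to 2.56 and that of Gpx5, an epididymal glutathione peroxidase, from -5.93 to 3.01. All 11 measured epididymis genes varied together, with a mean pairwise r of 0.92, or 0.38 without the 48 arrays. Eif2s3y levels also fell into separate clusters, of 142 mice at or below -4.16 and 153 mice at or above -0.10, and all 48 arrays belonged to the 153. The markers disagreed for 1 mouse, number 310, whose Eif2s3y level was -0.10 and whose Kdm5d level, at -3.02, lay below the highest of the 142 (-1.69). Of the 153, 27 had Eif2s3y levels of at most 0.45 and the rest at least 0.62, a gap seen after the values. All 27 had mouse numbers from 146 to 310, a range that holds 73 Eif2s3y-high mice. They came partly in runs and include every mouse numbered 146 to 153 and 196 to 199. Whether those arrays were processed apart is not given in the labels and was not tested. Without the 48 arrays, 6 of the 20 most variable genes remained among the top 20, and the SD of Lcn8 was 0.48 and that of Crisp3 1.58. Because of these clusters, correlations are also given for 3 sets of mice, the 142 Eif2s3y-low mice, the 105 Eif2s3y-high mice without epididymis transcripts and the 48 with them.

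**Figure D1:**
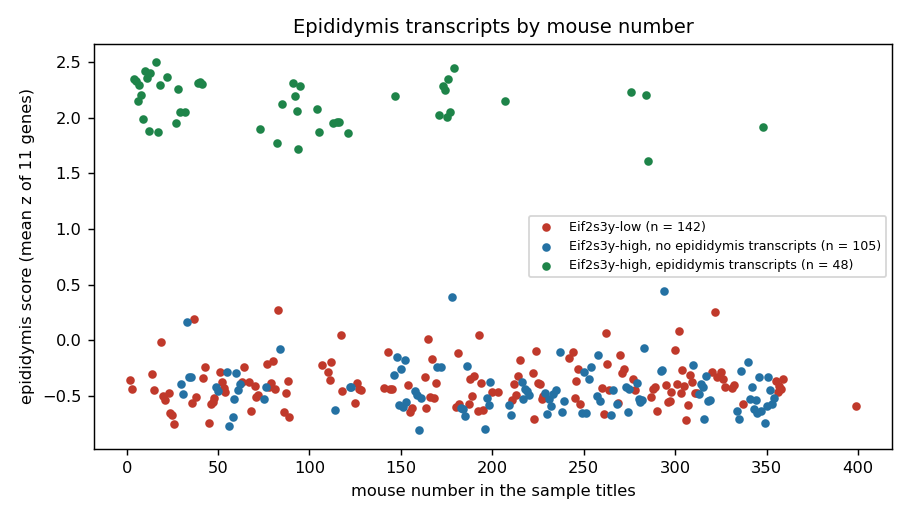
Epididymis score (mean z-score of 11 genes, vertical axis) of each mouse against the mouse number in its sample title (horizontal axis), 1 point per mouse, coloured by set of mice. The 48 arrays at 1.61 or above lie apart from the other 247, at 0.45 or below.

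Members of most fixed lists varied together from mouse to mouse more than random genes of like SD, though some members did not follow their list. Macrophage genes had a mean pairwise r of 0.73 over 22 genes, led by Tyrobp, Adgre1 and Cd68, which followed the rest of the list with r of 0.97, 0.96 and 0.96. Adipocyte genes had a mean r of 0.63 over 11 genes, led by the lipid droplet gene Plin1 (r = 0.90), G0s2 (0.85) and Lpin1 (0.83). Cell cycle genes had a mean r of 0.54, with Birc5, Ccna2 and Top2a at 0.94, 0.91 and 0.91, and fatty acid synthesis 0.44, with Fasn, Scd1 and Acaca at 0.89, 0.82 and 0.81. Among 27 lists, 23 exceeded random lists of like SD (adjusted p of at most 0.0231, one-sided, Benjamini-Hochberg over lists). The share of members with r above 0.3 to the rest of their list varied. It was 21 of 22 for macrophages, where Ctss had -0.09, and 11 of 11 for adipocytes. For immediate early genes it was 9 of 14 and for the evening arm of the clock 5 of 9.

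The other lists past the test had a mean r of 0.90 (exocrine pancreas, Prss1 and Cpb1 alone), 0.66 (MHC class 2, led by H2-DMa), 0.60 (B cell, led by Cd79b), 0.57 (skeletal muscle, led by Mylpf), 0.55 (fatty acid oxidation, led by Cpt2), 0.48 (epithelium, led by Krt18), 0.47 (endothelium, led by Esam), 0.45 (ribosomal proteins, led by Rpl3), 0.41 (extracellular matrix, led by Col5a2), 0.39 (T cell, led by Cd8a), 0.39 (interferon response, led by Ifit3), 0.39 (erythrocyte, led by Alas2), 0.37 (oxidative phosphorylation, led by Cox5b), 0.36 (thermogenic, led by Cpt1b), 0.31 (adipose expansion, led by Mest), 0.30 (cholesterol synthesis, led by Cyp51), 0.21 (immediate early, led by Egr1) and 0.16 (evening arm of the clock, led by Dbp). Those that did not pass were acute phase (mean r = 0.17, adjusted p = 0.0543), liver (0.10, adjusted p = 0.0599), the morning arm of the clock (0.09, adjusted p = 0.181) and heat shock (0.00095, adjusted p = 0.395). Without the 48 arrays with epididymis transcripts, acute phase (mean r = 0.22, adjusted p = 0.00527) and liver (0.12, adjusted p = 0.029) passed, and adipose expansion did not (0.20, adjusted p = 0.0503).

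Of the list scores, those of the acute phase and of adipose expansion followed Lep, a hormone gene of fat cells, most closely. Orm2 and Orm1, which encode orosomucoids, rose with r of 0.75 and 0.69 (n = 295), by 0.84 ± 0.04 and 1.04 ± 0.06 log2 units (SE) per log2 unit of Lep. Tspan17, Degs1, Mstn, Cavin1 and Lgals1 ranked between Orm2 and Orm1, with r between 0.70 and 0.72. Cyp2c23, Tuba1b, Thnsl2, Tmem135 and Mbnl2 came after Orm1, with r between 0.66 and 0.69. Mstn encodes myostatin and Cavin1 a coat protein of caveolae. Khsrp (r = -0.62), Myb (-0.61) and Lrfn4 (-0.61) were the most negative, and Zmym3, Itpr3, Cbx3, Rbbp6, Tg, Nav2, Rp9, Wdr46 and PRR6 followed with r between -0.60 and -0.57. Apoe did not pass (r = 0.05, adjusted p = 0.460).

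All 11 adipocyte genes rose with Lep, among them Dgat2 (r = 0.54), Gpd1 (0.52) and Pparg (0.50), and the count was also 11 adjusted over the list alone. Of 4 adipose expansion genes 3 rose, Npr3 (0.63), Mest (0.60) and Sfrp5 (0.46), and 3 adjusted over the list alone. Of 8 acute phase genes 6 rose and 2 fell, with Steap4 at 0.64, and counts adjusted over the list alone were also 6 and 2. Endothelial genes rose in 10 of 12 cases (Cdh5 at 0.54) and extracellular matrix genes in 11 of 17 with 1 lower (Col4a1 at 0.62), with the same counts adjusted over the list alone. B cell genes fell in 7 of 9 cases (Ighm at -0.30), or 8 adjusted over the list alone. Immediate early genes went both ways, 5 higher and 5 lower of 14, with Ier3 at -0.53 and Nr4a1 at -0.53. Over all mice, 11 of 11 epididymis genes and 11 of 14 epithelium genes passed as lower, with 2 epithelium genes higher, also adjusted over the list alone, counts that include the 48 arrays with epididymis transcripts. Without those arrays the epididymis score had r = 0.03 with Lep (adjusted p = 0.668), and within the 3 sets 0.07, 0.01 and 0.01 (adjusted p = 0.554, 0.893 and 0.937). The epithelium score had -0.25, -0.11 and -0.09 (adjusted p = 0.00859, 0.329 and 0.761). Of 22 macrophage genes 10 rose and 12 did not pass, also adjusted over the list alone, with Ccl2, a monocyte chemokine, highest at r = 0.28 (0.57, 0.13 and -0.12 within the 3 sets).

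The limma fit called 8868 probes higher and 6475 lower with Lep of 22893 tested (Benjamini-Hochberg adjusted p under 0.05). With array medians removed the higher share of calls was 48.0% in place of 57.8%, so the balance of higher and lower probes depends on centring. At an absolute r of at least 0.4, 1680 were higher and 877 lower. At that size they numbered 873 and 1049 with array medians removed, 420 and 547 with the first principal component as a covariate, and 675 and 750 without the arrays with epididymis transcripts.

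Lep followed the acute phase score most closely of the 25 lists other than epididymis and epithelium (r = 0.65, rho = 0.63, each with p = 1e-05 and adjusted p = 2.25e-05, n = 295), and r was 0.65 without the 2 mice farthest from the median of Lep. Within the 3 sets of mice it was 0.65, 0.68 and 0.66, and within the lower, middle and upper ranges of mouse number 0.60, 0.69 and 0.64. The acute phase list had not passed the coherence test over all mice (mean r = 0.17, adjusted p = 0.0543), though it did without the arrays with epididymis transcripts. Its members Lcn2 and Cp had r of -0.31 and -0.28 with the rest of the list, so the score does not stand for every member. The adipose expansion score followed Lep with r = 0.61 and rho = 0.54, adjusted p = 2.25e-05 each, 0.58 without the 2 farthest mice, 0.43, 0.61 and 0.76 within sets and 0.59, 0.64 and 0.48 within ranges of mouse number. For the adipocyte score r was 0.44 and rho 0.36, adjusted p = 2.25e-05 each, 0.42 without the 2 farthest mice and 0.44, 0.46 and 0.35 within ranges of mouse number. Within the Eif2s3y-low mice it was 0.11 (adjusted p = 0.353), against 0.51 and 0.78 in the other sets. The endothelium score had r = 0.43 and rho = 0.38, adjusted p = 2.25e-05 each, 0.41 without the 2 farthest mice and 0.42, 0.45 and 0.29 within ranges of mouse number. In the 3 sets it was 0.08 (adjusted p = 0.471), 0.49 and 0.72. The morning arm of the clock had r = 0.39 and rho = 0.42, adjusted p = 2.25e-05 each, 0.40 without the 2 farthest mice, 0.31, 0.33 and 0.13 within sets (adjusted p = 0.606 in the last) and 0.36, 0.20 and 0.41 within ranges of mouse number (adjusted p = 0.0894 in the middle). That list had not passed the coherence test (mean r = 0.09, adjusted p = 0.181), and 3 of its 5 genes rose with Lep. Fatty acid synthesis had r = 0.35 and rho = 0.34, adjusted p = 2.25e-05 each, 0.33 without the 2 farthest mice, 0.06 (adjusted p = 0.6), 0.52 and 0.72 within sets and 0.37, 0.36 and 0.37 within ranges. Cholesterol synthesis had r = 0.34 and rho = 0.29, adjusted p = 2.25e-05 each, and 0.32 without the 2 farthest mice. It passed in all 3 sets, with 0.33, 0.58 and 0.45 (adjusted p = 0.00045, 3.37e-05 and 0.00597), and gave 0.21 (adjusted p = 0.0622), 0.51 and 0.38 within ranges. For the extracellular matrix score r was 0.33 and rho 0.30, adjusted p = 2.25e-05 each, 0.31 without the 2 farthest mice and 0.42, 0.24 and 0.08 within ranges of mouse number (adjusted p = 0.591 in the upper). In the 3 sets it was 0.49, 0.04 and 0.03 (adjusted p = 0.749 and 0.893 in the last 2), with Col5a2 at 0.61, 0.14 and 0.05 and Col4a1 at 0.63, 0.50 and 0.56. The B cell score fell with Lep (r = -0.20, rho = -0.16, p = 0.0004 and 0.00582, adjusted p = 0.000771 and 0.0105), with -0.16 without the 2 farthest mice and -0.10, -0.34 and -0.24 within ranges of mouse number. It was -0.05 in Eif2s3y-low mice (adjusted p = 0.6) and -0.56 and -0.39 in the other sets. Without the arrays with epididymis transcripts r fell to 0.25 for the adipocyte score, 0.23 for endothelium and 0.21 for fatty acid synthesis. There it was 0.66 for acute phase, 0.51 for adipose expansion, 0.32 for the morning arm of the clock and 0.43 for cholesterol synthesis. For extracellular matrix it was 0.28 and for B cells -0.23, with adjusted p of at most 0.00198 for all of these lists.

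The macrophage score and Lep gave r = 0.12 over all mice (rho = 0.09, p = 0.04 and 0.108, adjusted p = 0.06 and 0.138), 0.12 without the 2 farthest mice, and 0.12, -0.03 and 0.07 within ranges of mouse number. With the Y-linked marker level as a covariate r was 0.22 (adjusted p = 0.000208), and without the arrays with epididymis transcripts 0.18 (adjusted p = 0.0081). Its sign differed between sets of mice: r was 0.46 in Eif2s3y-low mice (adjusted p = 6.75e-05), -0.28 in Eif2s3y-high mice without epididymis transcripts (adjusted p = 0.00940) and -0.37 in those with them (adjusted p = 0.0306). In the Eif2s3y-high mice without epididymis transcripts it was -0.30 without mouse 310 (n = 104, permutation p = 0.00245) and -0.26 without the mice of lower Eif2s3y level (n = 81, permutation p = 0.0209). Of 27 lists 17 were called with Lep, 13 positive and 4 negative, where 2 of the negative lists, epididymis and epithelium, were set apart and have no pooled r here. Without the arrays with epididymis transcripts, oxidative phosphorylation (r = 0.06), fatty acid oxidation (0.04), heat shock (0.13) and epididymis (0.03) were not called. There the thermogenic (-0.23), evening clock (-0.23), interferon (-0.19) and T cell scores (-0.15) were called as negative and the macrophage score as positive (adjusted p of at most 0.0234). The p of 1e-05 is the smallest that 100000 permutations can give.

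**Figure D2:**
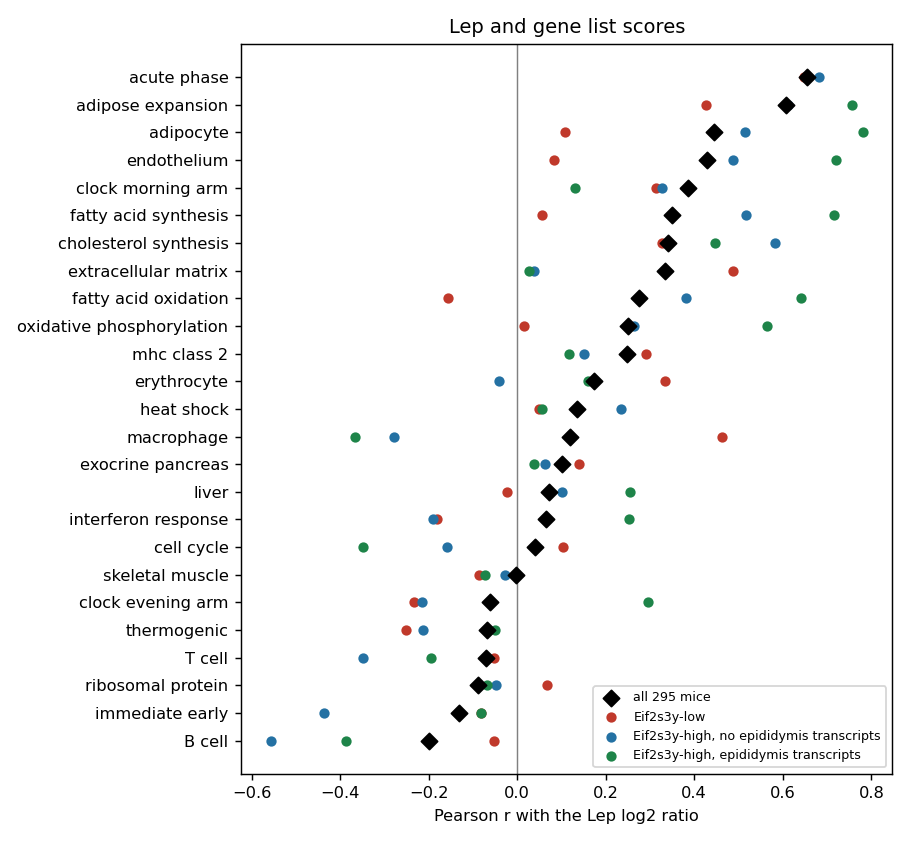
Pearson r (horizontal axis) of Lep with each of 25 list scores (vertical axis), for all 295 mice (diamonds) and within the 3 sets of mice (circles). The acute phase score lies at 0.65 over all mice, and the macrophage score at 0.46, -0.28 and -0.37 within sets.

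**Figure D3:**
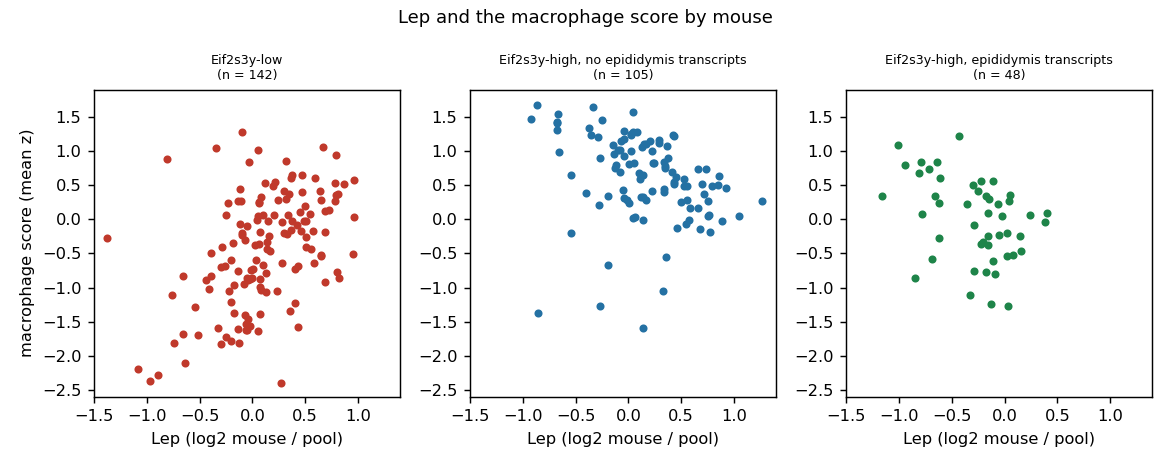
Macrophage score (mean z-score, vertical axis) against the Lep log2 ratio (horizontal axis), 1 point per mouse, in 3 panels for the 142 Eif2s3y-low mice and the 105 and 48 Eif2s3y-high mice without and with epididymis transcripts. The correlation within the panels is 0.46, -0.28 and -0.37.

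Adipocyte and fatty acid synthesis genes fell with the macrophage score. Outside the macrophage list, Dpep2 and P2ry6 had r of 0.97 with the score (n = 295), and Clec4a2, Slc15a3, Slc11a1, Myo1f, Rgs1, Tbxas1, Evi2a, Arhgap25, ARL11 and Cd200r1 had r between 0.95 and 0.96. Ddt (r = -0.78), Grhpr (-0.78) and Dnajb2 (-0.78) were the most negative, followed by Myh10, Rhbdl1, Oxnad1, Cyp2e1, Thtpa, Nrbp2, Uck2, Zfp503 and Fn3k with r between -0.77 and -0.73. Within the 3 sets of mice Fn3k had r of -0.73, -0.53 and -0.07, and the other negative genes named lay between -0.86 and -0.35. Cyp2e1, a cytochrome P450 of the liver list, fell by 1.47 log2 units per unit of score (SE 0.08). Apoe fell (r = -0.32, adjusted p = 8.36e-08).

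All 11 adipocyte genes fell with the macrophage score, among them the insulin-responsive glucose transporter gene Slc2a4 (r = -0.70), Car3 (-0.60) and Retn (-0.57), and 11 adjusted over the list alone. Fatty acid synthesis fell in 13 of 14 cases (Mlxipl at -0.63), fatty acid oxidation in 8 of 9 (Cpt2 at -0.59), oxidative phosphorylation in 7 of 8 (Ndufa10 at -0.62) and thermogenic genes in 13 of 16 (Ppara at -0.62), and counts of genes that fell were the same adjusted over the list alone. Within the 3 sets the thermogenic score had r of -0.48, -0.06 and 0.11 with the macrophage score (adjusted p = 0.739 and 0.663 in the last 2). Cell cycle genes rose in 15 of 17 cases (Cenpa at 0.81), extracellular matrix in 13 of 17 with 1 lower (Mfap5 at 0.75, Timp1 at 0.75) and MHC class 2 in 5 of 5 (H2-DMb1 at 0.73), again with the same counts adjusted over the list alone. Immediate early genes rose in 8 of 14 cases and fell in 2, with the same counts adjusted over the list alone, and with Atf3 at 0.89 and Fos at 0.81. Among clock genes, Arntl of the morning arm had r = 0.57 and Dbp of the evening arm -0.56. Within the 3 sets Arntl had 0.48, 0.31 and 0.42, and Dbp -0.69, -0.23 and -0.06. The evening arm score had -0.55, -0.23 and -0.14 (adjusted p = 0.0529 and 0.541 in the last 2) and the morning arm 0.34, 0.09 and 0.29 (adjusted p = 0.536 and 0.144 in the last 2). Il7r and Blnk, markers fixed for T and B cells, had r of 0.94 and 0.93 with the macrophage score, and 0.18 and 0.37 with the rest of their own lists. T cell genes rose in 7 of 13 cases and fell in 1 (median r = 0.15), and B cell genes rose in 5 of 9 (median r = 0.13), with the same counts adjusted over the list alone. Cholesterol synthesis genes rose in 8 of 14 cases and fell in 1, and adipose expansion genes fell in 1 of 4, with the same counts adjusted over the list alone. Within the 3 sets the adipose expansion score had r of 0.15 (adjusted p = 0.131), -0.70 (5.24e-05) and -0.54 (0.000675) with the macrophage score, and Mest 0.22, -0.55 and -0.56. The cholesterol synthesis score had 0.13, -0.0012 and -0.19 (adjusted p = 0.214, 0.993 and 0.39).

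The limma fit called 5930 probes higher and 6666 lower of 22872, and 1985 and 1632 at an absolute r of at least 0.4. With the Y-linked marker level as a covariate it called 6938 higher and 6217 lower. Of these, 4671 and 4631 were also called with that sign without the covariate, and 57 were called with the opposite sign. Among markers of other tissues, skeletal muscle genes fell in 12 of 14 cases and rose in 1, and endothelial genes fell in 10 of 12, with the same counts adjusted over the list alone. Within the 3 sets, however, the skeletal muscle score had r of -0.09, -0.13 and -0.05 with the macrophage score (adjusted p = 0.407, 0.321 and 0.836), and none passed. The endothelium score had -0.43, -0.63 and -0.34 (adjusted p = 0.0675 in the last). Epithelium genes fell in 8 of 14 cases and rose in 1, or 10 and 1 adjusted over the list alone, and their score had -0.31, -0.26 and -0.22 within sets (adjusted p = 0.305 in the last). No epididymis gene passed of 11.

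The adipocyte and fatty acid synthesis scores moved together and against the macrophage score. The pairs named here were chosen after their values were seen. The T and B cell scores had the highest r of any pair (0.89, rho = 0.80), with 0.87 without the 2 farthest mice, 0.93, 0.82 and 0.91 within the 3 sets of mice and 0.86, 0.92 and 0.84 within ranges of mouse number. The adipocyte score followed the endothelium (r = 0.86, rho = 0.84), fatty acid oxidation (0.85, rho = 0.85) and fatty acid synthesis scores (0.82, rho = 0.82), and r stayed at 0.85, 0.85 and 0.82 without the 2 farthest mice. The macrophage score followed MHC class 2 (r = 0.72, rho = 0.69), the cell cycle (0.57, rho = 0.65) and extracellular matrix (0.56, rho = 0.62), and opposed fatty acid synthesis (-0.58, rho = -0.54), oxidative phosphorylation (-0.56, rho = -0.55) and the adipocyte score (-0.54, rho = -0.58). For the adipocyte and macrophage scores r was -0.54 without the 2 farthest mice, -0.55, -0.77 and -0.53 within the 3 sets and -0.52, -0.65 and -0.69 within ranges of mouse number. The thermogenic and macrophage scores had r = -0.48 (rho = -0.40) over all mice, which did not hold in the Eif2s3y-high sets. The endothelium score opposed ribosomal proteins (r = -0.57, rho = -0.59). In the Eif2s3y-high mice with epididymis transcripts this r was -0.32 (adjusted p = 0.0925), and that of oxidative phosphorylation and macrophages -0.32 (adjusted p = 0.0904). Each pooled r and rho named had p = 1e-05, the smallest possible, with adjusted p = 2.62e-05 for r and 2.56e-05 for rho over 351 pairs. Of 351 pairs, 225 passed (111 positive, 114 negative), and 185 of the 300 pairs without the epididymis and epithelium lists.

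Genes next to each other on a chromosome varied together more often than genes on different chromosomes. Among 10598 adjacent pairs, 1051 had an absolute r of at least 0.5, 866 of them positive. That is 9.92%, against 6.62% of pairs on different chromosomes with like SD, and at most 7.19% in 1000 random gene orders (p = 0.001, the smallest possible). The strongest pairs without a shared symbol root were Lilr4b and Lilrb4a, immune receptor genes on chromosome 10 (r = 0.98), Mpped1 and Sult4a1 on 15 (0.95), Ptgds and Lcn12 on 2 (0.94), Tgm3 and Tmc2 on 2 (0.94), and Pira1 and Lilra6 on 7 (0.93). Rlim and Uprt on X (0.93), Serhl and Rrp7a on 15 (0.92), Prr14l and Depdc5 on 5 (0.92), Josd1 and Gtpbp1 on 15 (0.91) and Ido1 and Adam18 on 8 (0.90) followed. Without the arrays with epididymis transcripts r fell to 0.58 for Ptgds and Lcn12 and to 0.29 for Ido1 and Adam18. After removal of 20 principal components, chosen after the data were seen, the share was 1.60% of adjacent pairs against 0.052%, and 0.58% of pairs 20 genes apart. There r was 0.77 for Lilr4b and Lilrb4a and 0.89 for Pira1 and Lilra6, and between -0.08 and 0.34 for the other 8 named pairs. The symbol root is only the letters that open a symbol, so it misses relatives such as the genes of those first 2 pairs. Shared probe sequence is not excluded for them.

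**Figure D4:**
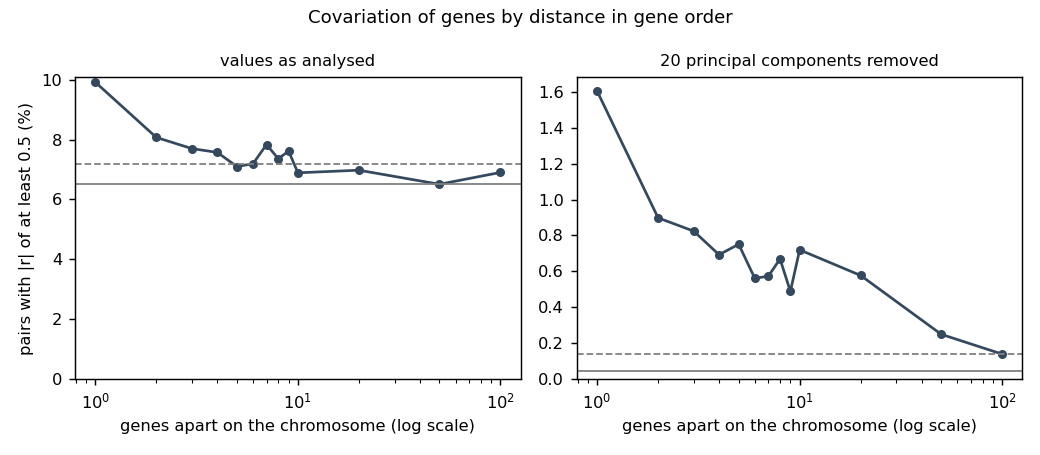
Share of gene pairs with an absolute r of at least 0.5 (vertical axis, percent) against the number of genes apart in chromosome order (horizontal axis, log scale), as analysed and with 20 principal components removed. Solid and dashed grey lines give the median and the highest share of adjacent pairs in 1000 random gene orders, 6.52% and 7.19% in the first panel.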

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

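Alternatives that use sets of mice by Eif2s3y or epididymis transcripts, that remove 20 principal components, or that leave out neighbours with probes of near identifiers, were chosen after the data were seen, and all others before. Of the counts and values that answer a comparison, 71 alternatives stayed within 1.5 times the value or within its spread and 24 moved. Array signals over background are not in the values used, so what they limit is unknown. The cause of each change was not tested, except where fewer mice, fewer probes or a stricter threshold entered.

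Variable probes numbered 4745 over the 10th to 90th percentile, 519 read as log2 and 1270 read as natural log. The slope of mean on variance was -1.46 over the most variable probes. For Lep covariation the probes called numbered 10016, 8691 and 9512 in the lower, middle and upper ranges of mouse number, 7687 above the median SD, 2557 at an absolute r of at least 0.4, 9032 in Eif2s3y-high mice without epididymis transcripts and 4079 in those with them. For macrophage covariation they numbered 8253, 8250 and 8208 in the 3 ranges, 6985 above the median SD, 3617 at an absolute r of at least 0.4 and 5232 in the Eif2s3y-high mice with epididymis transcripts. Lists called with Lep numbered 11 in Eif2s3y-low mice and 11 in Eif2s3y-high mice with epididymis transcripts. Calls among list pair correlations numbered 143 in the upper range of mouse numbers, and 132 and 75 in Eif2s3y-high mice without and with epididymis transcripts. Pairs called with the opposite sign to that over all mice numbered 14 with the first principal component as a covariate, 5 without the epididymis arrays, 1 in Eif2s3y-low mice, 2 in Eif2s3y-high mice, 1 each in those without and with epididymis transcripts, and 2 with the lists' own principal components. The neighbour ratio was 30.6 with 20 principal components removed and 25.1 with pairs of a shared symbol root left out too.

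Correlations with Lep that changed sign follow. For the epididymis score, whose values over all mice contrast the 48 arrays with the rest, r was 0.306 with the first principal component as a covariate (adjusted p = 4.5e-05), 0.034 without the epididymis arrays, 0.066 in Eif2s3y-low mice, and 0.013 and 0.012 in Eif2s3y-high mice without and with epididymis transcripts, and for the epithelium score it was 0.039 with the first principal component. For Lep with the interferon response (0.06 over all mice) r was -0.012 with array medians removed, -0.249 with the first principal component as a covariate, -0.0098 with the Y-linked level, -0.025 and -0.131 in the middle and upper ranges, -0.186 without the epididymis arrays, -0.182 in Eif2s3y-low mice and -0.190 in Eif2s3y-high mice without epididymis transcripts. For Lep with the cell cycle r was -0.0048 with array medians removed, -0.034 with the first principal component, -0.108 in the middle range, -0.014 in Eif2s3y-high mice, and -0.158 and -0.349 in those without and with epididymis transcripts. For Lep with the macrophage score r was -0.025 in the middle range, -0.062 in Eif2s3y-high mice, and -0.278 and -0.367 in those without and with epididymis transcripts. With the first principal component r with Lep was -0.0058 for oxidative phosphorylation, -0.0019 for fatty acid oxidation and 0.087 for ribosomal proteins. Ribosomal proteins gave 0.021 without the epididymis arrays and 0.067 in Eif2s3y-low mice, where fatty acid oxidation gave -0.157 and liver -0.023. The evening arm of the clock gave 0.102 and 0.019 in the lower and middle ranges, 0.042 in Eif2s3y-high mice and 0.294 in those with epididymis transcripts. Skeletal muscle gave 0.0055 in the lower range, 0.046 in even mouse numbers and 0.0041 with the list's principal component. Thermogenic genes gave 0.021 and T cells 0.045 in the lower range, liver -0.016 in the upper range, and erythrocytes -0.042 in Eif2s3y-high mice without epididymis transcripts. For Apoe with Lep r was -0.0073 with array medians removed, -0.201 with the first principal component, -0.116 in the upper range, -0.137 without the epididymis arrays, -0.219 in Eif2s3y-low mice and -0.00036 in Eif2s3y-high mice without epididymis transcripts.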

Other observations

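All tests of epididymis arrays, of Lep with the macrophage score and of reassigned regressors were chosen after the results were seen, as were the settings for neighbouring genes that leave out the epididymis arrays or remove 20 principal components, while the other tests of neighbouring genes were chosen before. Some list scores had long upper tails. The exocrine pancreas score had a 95th percentile of 1.12 and a maximum of 5.88, skeletal muscle 1.45 and 4.88, erythrocytes 1.04 and 4.31, liver 0.52 and 3.38, B cells 1.55 and 3.97, T cells 1.12 and 3.24 and the cell cycle 1.10 and 3.09. The macrophage score had 1.24 and 1.67, epithelium 1.39 and 1.72, and epididymis 2.29 and 2.50. Mmp12 ran from -6.32 to 1.61 on the log2 scale, Adgre1 from -3.04 to 1.46 and Cd68 from -2.40 to 1.29.

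Without the 48 arrays with epididymis transcripts, the most variable genes after Eif2s3y were Sult1e1 (SD 2.85), Mgarp (2.66), Kdm5d (2.59), Hsd3b1 (2.59), Pcp4 (2.32), Upk3a (2.15) and Hao2 (2.15), named after their values were seen. Akr1c18, Cyp11a1 and Hsd17b1, genes of steroid enzymes also picked after the values were seen, had SDs of 2.08, 1.97 and 1.78, and no list of such genes was tested. Pitx1, a homeobox gene, had 1.91, and Hoxa11 2.10. Fitted with the product of Lep and the Y-linked marker level, 4651 probes had a positive and 2809 a negative product term past an adjusted p of 0.05 of 22893.

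The 48 arrays with epididymis transcripts are the first pattern. All 48 were among the 153 Eif2s3y-high mice, 34 of 52 such mice with numbers up to 118, 10 of 50 from 121 to 247 and 4 of 51 from 248 to 399. The share differed over these ranges of mouse number (permutation p = 1e-05, the smallest possible), so a period of collection is a candidate explanation. If tissue was carried over at dissection, the epididymis score may fall as the adipocyte score rises. Within the 48 arrays r was -0.27 (permutation p = 0.0666, rho = -0.26, p = 0.0687, n = 48), and the test does not decide. The 2 scores had r = -0.59 over all mice and -0.59 within Eif2s3y-high mice (permutation test, adjusted p = 2.62e-05 and 3.9e-05). Without the 48 arrays r was -0.05 (adjusted p = 0.566). Adipocyte transcripts were thus lower in the 48 arrays than in the others, which carry-over would give. Other differences between those mice could give it too. No biological explanation was tested.

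The covariation of neighbouring genes is the second. Random gene order is argued against, since 9.92% of adjacent pairs passed and no random order exceeded 7.19%, and structure over all arrays is too, as the whole cause only: with 20 principal components removed 1.60% of adjacent pairs passed, or 170 pairs in place of 1051, against 0.052% on different chromosomes, a ratio of 30.6. Related genes with shared probe sequence stay open, since the ratio was 1.31 without pairs of a shared symbol root, between the bounds set beforehand. A shared root also misses relatives such as Lilr4b and Lilrb4a or Pira1 and Lilra6. Without the arrays with epididymis transcripts the ratio was 1.38, between the same bounds, which does not decide. A second test, chosen after the results were seen, argues against those arrays as the whole cause. Without them 10.4% of adjacent pairs passed, where no random order exceeded 8.39%. Haplotype blocks that segregate in the cross may contribute: 7.14% of pairs 5 to 20 genes apart passed, above the highest random order of 6.70%. The share was 7.00% without pairs of a shared symbol root, a rule that misses some relatives. At 50 and 100 genes apart 6.51% and 6.90% passed, against a median of 6.52% for adjacent pairs in random orders. With 20 components removed these shares were 0.25% and 0.14%, against a median of 0.047%. Clusters of related genes are not told apart from haplotype blocks here. For adjacent pairs, the ratio was 25.1 with 20 components and pairs of a shared symbol root both removed. That ratio still includes relatives such as Lilr4b and Lilrb4a or Pira1 and Lilra6, and it does not test distance.

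The relation of Lep with the macrophage score is the third. The product term of Lep and the Y-linked marker level on the macrophage score was -0.159 ± 0.030 (SE, n = 295, permutation p = 1e-05) and -0.207 ± 0.033 without the arrays with epididymis transcripts (n = 247, p = 1e-05), so those arrays do not account for it. Without mouse 310 as well it was -0.207 ± 0.033 (n = 246), and without the remaining mice of lower Eif2s3y level -0.199 ± 0.035 (n = 223), with p = 1e-05 each. The term measures a difference already seen between the sets of mice and does not test its cause. Both markers are Y-linked, and their clusters agree for all but mouse 310, so their level cannot be told apart from sex here. Sex, age at collection and fat depot are not given per mouse, and each stays open as a cause.

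Chance assignment of the regressor over all mice is argued against for both fits. The real Lep fit called 15343 probes and the highest of 100 reassignments 822, and the macrophage fit 12596 against 2. Of 101 assignments 1, the real one, reached each real count. Reassignment over all mice also breaks the sets of mice and the structure shared over arrays. The counts therefore do not show that probes follow Lep or the macrophage score in particular.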
